A study of Mus musculus with 10 samples.

How the data were processed

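RNA was measured by sequencing in 10 libraries of mouse embryos, each made from 10 morulae. Per the labels' protocols, embryos from in vitro fertilization received an injection of an antisense oligonucleotide (ASO) at 3 to 6 h after insemination and were grown to the morula stage at 72 h. The oligonucleotide either targeted Mettl3 (Mettl3-ASO, 5 libraries) or had no target (ASO-Control, 5 libraries). Libraries were built from polyadenylated RNA with the SMART-Seq v4 PLUS kit, which amplifies full-length cDNA. The labels mark replicates 3 to 5 of both groups as batch 2 and give replicates 1 and 2 no batch; these 4 are called untagged here. Groups and replicate numbers came from the sample titles. The labels do not say whether the embryos of different libraries came from separate fertilizations, so p-values measure the spread between these libraries, which may be technical.

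The deposited files are one gene table per library with the columns that RSEM writes. Per the submitters' processing notes, the tools were STAR 2.7.10 and RSEM 1.3.3 and the genome build was mm10; the notes give no role, order or options. Whether the counting used strand is not given in the sources used here, nor is the annotation release. The authors deposited expected counts, which are estimates of reads per gene in which reads that match several genes are shared out, and which need not be whole. The deposited TPM values are scaled by the authors to a common sum per library, and the deposited FPKM values to transcript length and the number of fragments. Length and effective length per gene, also deposited, are means over transcripts weighted by their estimated abundance. Each table lists 24411 genes by symbol. Mitochondrially encoded transcripts were not analysed here, so their share of the total, their gene list and a rescaling without them were not run. Multi-mapped reads shared out by estimation make values of near-identical gene copies uncertain, and FPKM depends on the composition of each library.

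Total expected counts were 9905830 to 13530284 in the 4 untagged libraries and 21412857 to 32327283 in the 6 libraries of batch 2. No library pair within a group and batch agreed within sampling noise: the lowest chi-square per degree of freedom over 8 such pairs was 25.0, so all 10 libraries counted as separate. Fragments carry no molecular identifiers, so counting intervals and floors cover counting error only. A gene with no counts in a group was set against a floor of 3 counts over the group; a gene with 1 to 3 counts was given as a ratio of summed CPM with a 95% exact interval.

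The plan, with its tests, gene lists, rule for named genes and most alternatives, was written before the data were examined. It assumed FPKM alone and a limma test; since the tables hold expected counts, the test it names for that case was used. Expected counts were rounded to whole numbers and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM scaling and a model with terms for batch and group. Genes with a mean FPKM of at least 1 over the 10 libraries were tested (9522 genes). Every adjusted p is a Benjamini-Hochberg value over those genes from this test unless another tool is named, and a gene is called at an adjusted p under 0.05 with no fold threshold. Fold changes are of Mettl3-ASO over ASO-Control, and their standard error is the absolute log2 fold change divided by the square root of the F statistic. The same test was run within each batch, and a further model tested the interaction of group and batch. The level of Mettl3 and the number of genes with an FPKM of at least 1 were compared by two-sided exact permutation tests that relabelled libraries within each batch; 120 relabellings allow no p below 0.0167. The correlation of fold changes between batches is across genes, which are not independent replicates, and was compared with 60 relabellings of groups within batches.

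Gene lists for 35 pathways, complexes and cell types were fixed in the plan, and 31 with at least 5 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01 between genes, adjusted over lists. camera with an estimated correlation and fry, which tests whether the members move on balance one way (or, in its mixed form, in either direction) without comparing them with other genes, were run beside it. Genes were named in the text by a rule fixed in the plan. It takes the m6A methyltransferase complex and the 3 members of each list with the smallest p. It also takes the 10 largest rises and 10 largest falls on the log2(FPKM + 1) scale among called genes with a mean FPKM of at least 5 in the higher group and one sign in both batches, passing over predicted and clone names (11 among the rises and 2 among the falls). Any other gene named was chosen after its values were seen, and is said to be.

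Both groups carry replicate numbers 1 to 5 in the titles. The deviations of same-numbered libraries from their group and batch means correlated across genes at 0.273 for numbers 1 and 2, where a batch of 2 per group makes the values equal, and at 0.174, 0.147 and 0.105 for numbers 3, 4 and 5. Each lies above 0.1, the limit set for treating the numbers as pairs, and 4 of 5 numbers correlated best with their own partner. Numbers 1 and 2 match their partners together or not at all, so this is weak support for pairs. The main tests kept the batch term of the plan. The pairing thus comes from the data; the labels do not state it. A fit with the replicate number as a block in place of the batch term was run for the tests of genes, gene lists, lengths and detected genes, and, chosen after the data were seen, for the interaction and the correlation between batches.

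Alternatives, whose effects the closing section gives, were DESeq2 1.42.0, limma on log2(FPKM + 1) with pseudocounts of 0.1 and 5, median-ratio, quantile and TPM scaling, no filter or a mean FPKM of at least 5, library weights, no batch term, an exact Wilcoxon test, each batch alone, and each library left out in turn. Coordinates and overlaps came from the GENCODE M21 annotation of GRCm38, the assembly that mm10 names, in which 9459 of the 9522 tested genes were found by symbol. The share of each gene's 50-base windows that also occur in another annotated gene was computed from the same annotation.

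The tests of genes and lists were tried on simulated counts drawn from the means and library sizes of the 9522 genes, with 200 genes changed by known folds. With all libraries, edgeR recovered 11.9% of genes changed 1.5-fold, 61.2% of those changed 2-fold and 93.9% of those changed 4-fold, with 3 false calls. Batch 2 alone recovered 20.9% of 2-fold and 84.8% of 4-fold changes. The untagged libraries alone recovered 0% of 2-fold and 51.5% of 4-fold changes. With 200 of 9522 genes changed, the Benjamini-Hochberg cut is stricter than where many genes change. These shares may thus understate recovery in the real data. The interaction test recovered 4.48% of 2-fold and 36.4% of 4-fold differences between batches. Of the calls DESeq2 made on the simulated counts, 14.7% were false. The exact Wilcoxon test recovered 0% of changes of each size, since its smallest p passes adjustment only where many genes change. edgeR called no gene, and camera and fry no list, when nothing was changed. The length test, on 2532 genes, recovered 181 of 200 changed genes with 10 false calls.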

Results

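Pools of 10 mouse morulae, the stage before the blastocyst, were profiled by RNA sequencing after injection of the zygote with an antisense oligonucleotide against Mettl3 or with a non-targeting one. Each group held 5 libraries, 2 untagged and 3 of batch 2. Total expected counts per library were 9905830 to 13530284 in the untagged libraries and 21412857 to 32327283 in batch 2. Correlations of log expression between libraries were 0.955 to 0.979 within ASO-Control, 0.912 to 0.963 within Mettl3-ASO and 0.815 to 0.905 between groups. The first principal component held 61.3% of the variance and had one sign in all ASO-Control libraries and the other in all Mettl3-ASO libraries. Mettl3-ASO replicate 1 lay nearest to the controls on it. The comparison addresses what Mettl3, which encodes the catalytic subunit of the enzyme that writes N6-methyladenosine (m6A) into RNA, does for mitochondria and chromatin in early embryos.

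Mettl3 itself was nearly absent after injection of its oligonucleotide. The gene lies on chromosome 14 at 52294841 to 52308741 (GRCm38). The mean level was 8.86 FPKM in ASO-Control, from 6.58 to 12.68 over 5 libraries, and 0.014 ± 0.0195 FPKM (SD, n = 5) in Mettl3-ASO. Replicates 1 to 3 of Mettl3-ASO held 0 counts, which allows up to 0.222, 0.303 and 0.108 CPM at 3 counts of each library's total, and replicates 4 and 5 held 2 and 1 counts. The control libraries held 244 to 446 counts each. Summed over libraries and divided by total depth, 1681 counts in ASO-Control against 3 in Mettl3-ASO gave a 471-fold lower level (95% interval 161 to 2288). The fitted log2 fold change was −8.72 ± 0.45 (SE; adjusted p = 6.6e-08), with −8.17 in batch 2. In batch 2 the Mettl3-ASO libraries held 3 counts together, 315-fold below the controls (95% interval 108 to 1530). In the untagged libraries they held none against 516, so that Mettl3 was at least 164-fold lower at a floor of 3 counts over the group. The two-sided exact permutation p was 0.0167, the smallest that 120 relabellings allow. Of the annotated exon bases of Mettl3, 18.4% overlap Tox4 on the opposite strand, and the site the oligonucleotide binds is not given in the sources used here.

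**Figure D1:**
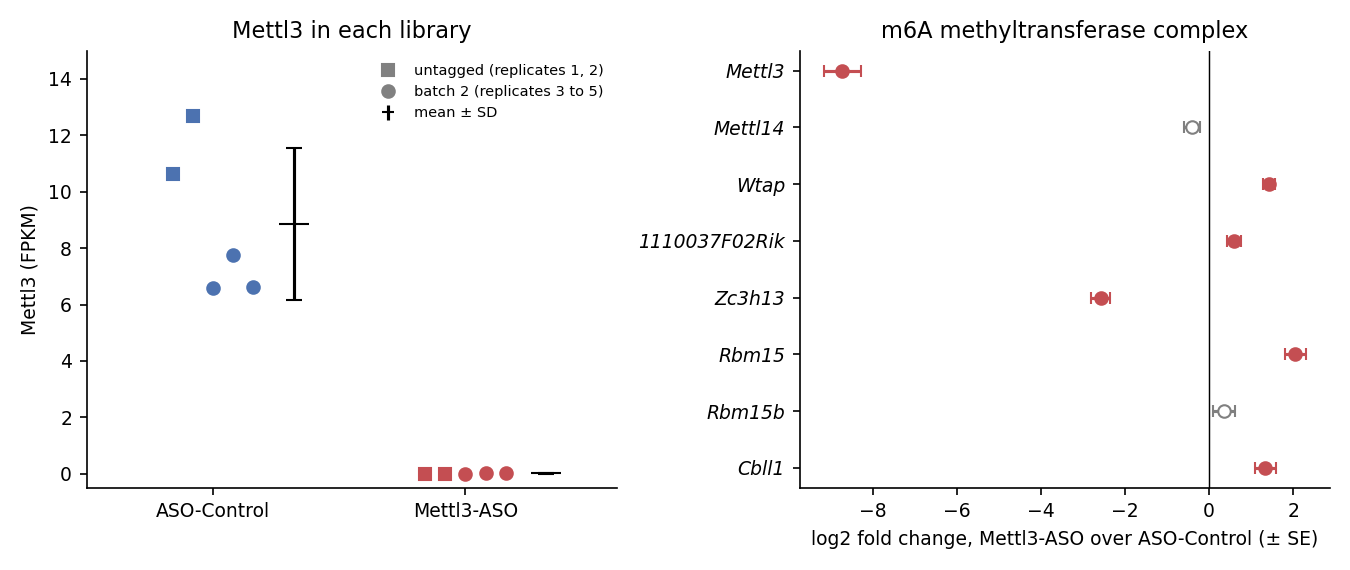
Left, Mettl3 in FPKM in each library, with the mean ± SD of 5 libraries per group; squares are untagged and circles batch 2 libraries. Right, log2 fold change of Mettl3-ASO over ASO-Control ± SE for the 8 genes of the methyltransferase complex, filled where the adjusted p is under 0.05. Mettl3 fell by 8.72 and Zc3h13 by 2.58, while Wtap, Rbm15, Cbll1 and 1110037F02Rik rose.

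The other subunits of the m6A methyltransferase complex moved in different directions. Rises and falls by a stated amount are on the log2 scale, with ± for the SE. Wtap, which anchors the complex in nuclear speckles, rose 2.68-fold in counts (adjusted p = 6.1e-06). Its FPKM, which also reflects a shorter estimated transcript length in Mettl3-ASO, went from 328 ± 52.0 to 1093 ± 165 (SD, n = 5). Rbm15, an RNA-binding adaptor, rose by 2.05 ± 0.25, and Cbll1 by 1.34 ± 0.24. 1110037F02Rik, annotated as Virma, rose by 0.59 ± 0.17 (adjusted p = 0.0134; 0.089 with limma under quantile scaling). Zc3h13, another adaptor, fell by 2.58 ± 0.23 (adjusted p = 4.0e-06). Mettl14, the partner of Mettl3 in the catalytic core, had a log2 fold change of −0.41 ± 0.20 (adjusted p = 0.104; 0.04 with limma under quantile scaling), and Rbm15b one of 0.36 ± 0.26 (adjusted p = 0.266). Among 15 tested readers and erasers of m6A, 5 rose and 4 fell. The reader Ythdf2 rose by 1.19 ± 0.12 and Rbmx by 1.96 ± 0.19, while the reader Igf2bp3 fell by 1.16 ± 0.20.

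Across the transcriptome, 4704 of 9522 tested genes (49.4%) were called, of which 2418 rose and 2286 fell. Counts of called members in the gene lists are to be read against this share. A change of at least 2-fold was seen in 1280 genes that rose and 826 that fell, and of at least 64-fold in 67 that rose and 3 that fell. Of the 67 genes that rose 64-fold, 30 carry predicted or clone names. Within batch 2 alone 3718 genes were called (1923 rose, 1795 fell), and within the untagged libraries alone 596 (361 rose, 235 fell). With the replicate number as a block in place of batch, 5246 genes were called over all libraries, 4205 in batch 2 and 2606 in the untagged libraries. The labels do not state these pairs. In the untagged libraries this fit leaves little to estimate spread from, so 2606 is not stronger evidence than the count without the block. The untagged count of 596 was 245 or 94 without ASO-Control replicate 1 or 2, and 2652 or 1063 without Mettl3-ASO replicate 1 or 2.

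Among the largest rises, Tdpoz4 rose 293-fold from 0.32 ± 0.272 to 104 ± 56.5 FPKM (SD, n = 5; adjusted p = 1.7e-06), and Tdpoz5 by 7.57 ± 0.60 on the log2 scale. Usp17lb rose by 8.97 ± 0.99, Pramef25 by 7.69 ± 0.67, BC080695 by 7.53 ± 0.72 and Zfp352 by 7.21 ± 0.76. All 28 control counts of Usp17lb lay in ASO-Control replicate 5, so its fold rests on that library. BC147527, AA792892 and BB287469 rose by 6.97, 6.82 and 6.65. Annotated sequence shared with other genes amounted to 100% of the 50-base windows of Tdpoz5, 96.6% for BB287469, 63.5% for Pramef25 and 7.09% for Zfp352, so the split of reads among copies is uncertain.

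Of the genes that fell, several are expressed in many cell types. Nubp1, which acts in iron-sulfur cluster assembly, fell by 6.37 ± 0.30 from 54.9 ± 3.70 to 0.67 ± 0.354 FPKM (SD, n = 5; adjusted p = 4.2e-08). Immp1l, which encodes a subunit of the inner mitochondrial membrane peptidase, fell by 5.55 ± 0.37. Faf1 fell by 4.40 ± 0.22, the helicase gene Ddx39 by 3.46 ± 0.17 and the 14-3-3 gene Ywhaz by 3.32 ± 0.17. Zfp934 fell by 4.99 ± 0.47 and Serpinb9b fell by 3.35 ± 0.26. The epithelial adhesion gene Epcam fell by 3.56 ± 0.26 and Dppa1 fell by 5.55 ± 0.71. Opposite-strand exons of Tvp23a overlap 36.9% of Nubp1 and those of Adgre5 17.4% of Ddx39, and 33.8% of the windows of Immp1l occur in other genes.

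Genes of the two-cell stage, when the mouse embryonic genome is first strongly transcribed, were higher in Mettl3-ASO morulae. All 21 tested members rose, with a median log2 fold change of 7.43 (also 7.43 with members of 3 or fewer counts at their bound). Of 24 measured members 21 passed the filter on mean FPKM over all libraries. A member near 0 in the controls could pass only if high in Mettl3-ASO, so the filter partly sets this count and median. Chosen after its values were seen, Usp17le had 12.65 FPKM in Mettl3-ASO replicate 1 and at most 1.27 in any other library. The list passed against all other genes at a preset correlation (adjusted p = 1.7e-14) but not with an estimated correlation (adjusted p = 0.181). With such members at their bound or ratio within each batch, the median was 6.69 in batch 2 and 7.86 in the untagged libraries, where 8 members had no counts in one group and 3 had 1 to 3. Gm5662 rose from 3.46 ± 1.06 to 1082 ± 518 FPKM (SD, n = 5; log2 fold change 8.24 ± 0.43, adjusted p = 6.6e-08). Tcstv3 rose from 3.47 ± 2.74 to 708 ± 545 FPKM and Gm8300 from 0.842 ± 0.637 to 216 ± 121 FPKM. Members were not equally high in every library. The summed Zscan4 family reached 480, 383 and 748 CPM in Mettl3-ASO replicates 1, 2 and 4, but 3.77 and 2.52 in replicates 3 and 5, within the control range of 0 to 5.31. Tcstv3 and Zfp352 together reached 132 to 1480 CPM in Mettl3-ASO and 0.637 to 8.17 in ASO-Control. Over 10 groups of genes that share sequence with the 21 tested members, summed counts had a median log2 ratio of 2.75, lower than the list's own median.

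**Figure D2:**
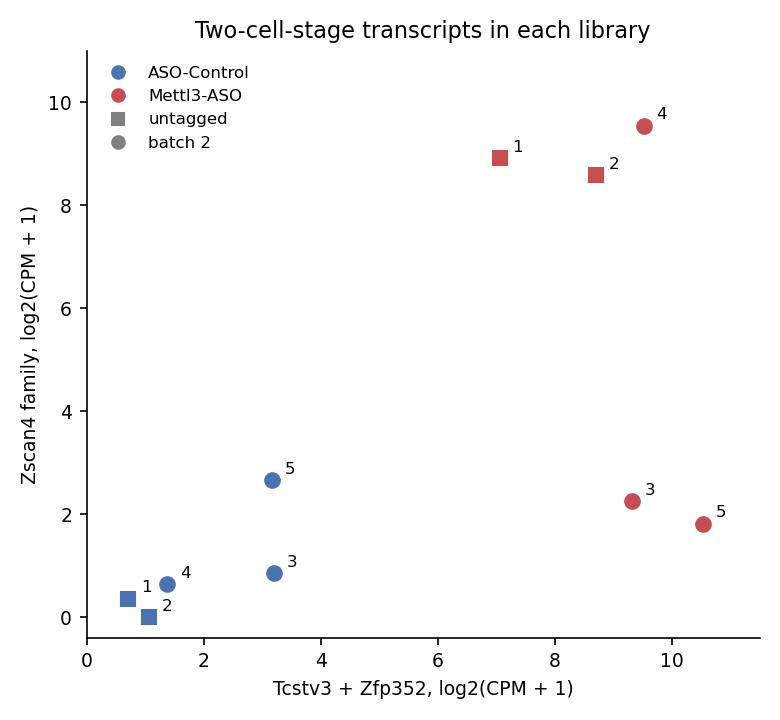
Summed Zscan4 family (vertical) against Tcstv3 plus Zfp352 (horizontal) in each library, both as log2(CPM + 1); numbers are replicates, squares untagged and circles batch 2 libraries. All 5 Mettl3-ASO libraries lie to the right of the controls, and replicates 3 and 5, at 3.77 and 2.52 CPM of Zscan4, lie at control height.

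Genes of the trophectoderm, the outer lineage that forms the placenta, were mostly lower. Of 20 tested members 14 fell and 1 rose, with a median log2 fold change of −1.31 (−1.28 in batch 2, −1.42 in the untagged libraries). The list's adjusted p was 1.6e-04 at a preset correlation and 0.617 with an estimated correlation. Dab2 fell by 2.14 ± 0.19 from 145 ± 10.9 to 33.9 ± 12.7 FPKM (SD, n = 5), and the tight junction gene Cldn6 by 2.92 ± 0.31. The transcription factor gene Hand1 rose by 2.26 ± 0.26. Chosen after their values were seen, the lineage factor gene Gata3 fell by 2.19 ± 0.37, and the keratin genes Krt8 and Krt18 by 2.12 ± 0.37 and 2.71 ± 0.38. Among 25 genes of compaction, polarity and junctions 9 fell and 2 rose. The cadherin-linked Ctnna1 fell by 2.39 ± 0.16, the polarity gene Pard3 by 2.50 ± 0.25 and Cldn7 by 1.01 ± 0.15. Mettl3-ASO replicate 1 lay apart in several of these genes, with Epcam at 79.2 FPKM, Cldn6 at 23.6 and Cldn7 at 228, against 15.5 to 21.6, 2.80 to 6.97 and 90.1 to 121 in the other 4 libraries of its group.

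Genes of the inner cell mass, the source of the embryo proper, moved both ways, with 7 of 18 rising and 5 falling. Their list did not pass against other genes (camera adjusted p = 0.487 at a preset correlation). By fry it moved on balance one way (adjusted p = 0.0141). Fgf4, a signal of pluripotent cells, rose 9.91-fold (log2 3.31 ± 0.35, adjusted p = 1.4e-05), and Sall4 rose by 0.75 ± 0.10. Lin28a fell by 1.36 ± 0.22. Chosen after their values were seen, Nanog rose by 1.07 ± 0.27 and Pou5f1 fell by 0.64 ± 0.15. Of 5 tested genes of the primitive endoderm, the yolk sac lineage, 2 fell. Lamc1 fell by 1.01 ± 0.28. Lamb1 fell by 0.93 ± 0.36 (adjusted p = 0.0462). Its adjusted p was 0.0579 to 0.109 without ASO-Control replicate 1, 3, 4 or 5 or Mettl3-ASO replicate 3, 4 or 5, and 0.0534 to 0.0727 with limma (all settings but median-ratio and quantile scaling and library weights), robust edgeR, no batch term or a mean FPKM of at least 5. Its log2 fold change was −1.45 without Mettl3-ASO replicate 1. Sparc had −0.63 ± 0.34 (adjusted p = 0.144; 0.0477 without Mettl3-ASO replicate 1 and 0.0418 under quantile scaling). Among 11 oocyte-deposited genes 5 rose and none fell (2 fell without Mettl3-ASO replicate 1), including the zona pellucida gene Zp3 by 2.26 ± 0.29, Npm2 by 1.48 ± 0.34 and Dppa3 by 0.62 ± 0.09. Dppa3 was the most abundant transcript in each library, and its call was lost with no batch term (adjusted p = 0.0796) and under quantile scaling (adjusted p = 1), which gives the highest gene of each library one value.

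Transcripts of glycolysis and of the tricarboxylic acid (TCA) cycle, which supply energy and carbon, were lower. In glycolysis, 11 of 15 tested genes fell and 2 rose, with a median log2 fold change of −1.19 (−1.17 in batch 2, −0.85 in the untagged libraries) and an adjusted p of 0.01 at a preset correlation (adjusted p = 0.617 with an estimated correlation). Eno1, the enolase gene, fell by 2.49 ± 0.29, Aldoa by 1.19 ± 0.14 and the glucose transporter gene Slc2a3 by 1.74 ± 0.29. Mettl3-ASO replicate 1 lay apart, with Aldoa at 266.5 FPKM (others of its group 103.88 to 138.92) and Slc2a3 at 20.34 (6.29 to 9.68). In the TCA cycle 11 of 21 fell and 3 rose, with a median of −0.31 and an adjusted p of 0.00666 (adjusted p = 0.617 with an estimated correlation). This call was lost in the untagged libraries (adjusted p = 0.077) and under quantile scaling (0.0577). Idh3a fell by 1.52 ± 0.13, Suclg1 by 1.32 ± 0.10 and Idh3g by 0.80 ± 0.10. The 3 lists of nuclear respiratory chain genes each moved on balance one way by fry, which does not compare them with other genes. The fry adjusted p was 0.00607 for complex I, 0.041 for complexes II to IV and 0.00161 for complex V. Against other genes, camera gave these lists adjusted p from 0.0747 to 0.366 at a preset correlation. The list of complex I passed without ASO-Control replicate 4 (0.0375), with limma at a pseudocount of 5 (0.0456), with limma under median-ratio scaling (0.0301) and with no filter (0.00109), and that of complex V passed at a pseudocount of 5 (0.046) and with no filter (0.00288). In complex I, 14 of 36 fell and 1 rose, with Ndufa9 falling by 1.20 ± 0.11, Ndufs4 by 1.07 ± 0.15 and Ndufs8 by 0.89 ± 0.11. In complexes II to IV, 9 of 26 fell and 4 rose, with Sdhc falling by 1.10 ± 0.14, Uqcrc1 by 0.93 ± 0.11 and Sdha by 0.91 ± 0.13. In complex V, 8 of 16 fell and 2 rose, with Atp5b falling by 0.95 ± 0.10, Atp5d by 0.89 ± 0.10 and Atp5g2 by 0.74 ± 0.13.

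Other mitochondrial lists were mixed, and their counts of called members stand beside 49.4% called among all tested genes. By fry, mitochondrial ribosomal proteins (adjusted p = 0.0286) and mitochondrial dynamics (0.002) moved on balance one way. Neither passed camera at a preset correlation (adjusted p = 0.289 and 0.366). The lists of mtDNA maintenance and antioxidants passed neither test (fry adjusted p = 0.55 and 0.343). Of 77 mitochondrial ribosomal protein genes 25 fell and 14 rose; Mrps10 fell by 1.42 ± 0.13, Mrps18b by 1.13 ± 0.09 and Mrpl47 by 1.03 ± 0.10. Of 19 genes of mitochondrial dynamics and mitophagy 7 fell and 3 rose. The mitophagy receptor gene Fundc1 rose 3.69-fold from 64.9 ± 7.81 to 247 ± 40.6 FPKM (SD, n = 5; adjusted p = 4.2e-07). The fission gene Dnm1l fell from 39.7 ± 2.88 to 20.8 ± 3.45 FPKM (SD, n = 5), and Chchd3, a cristae organizer, fell by 1.66 ± 0.25. Of 17 genes of mtDNA maintenance and biogenesis 3 rose and 3 fell; the mitochondrial RNA polymerase gene Polrmt rose by 1.08 ± 0.20, Pprc1 by 0.99 ± 0.18 and Tefm by 0.59 ± 0.12 (adjusted p = 0.106 with no batch term). The 25 antioxidant genes split evenly, 6 up and 6 down. Sod2, the mitochondrial superoxide dismutase gene, fell by 1.31 ± 0.13 and Txn2 by 0.87 ± 0.13, while Gclc of glutathione synthesis rose by 1.34 ± 0.19. Mitochondrially encoded transcripts were not analysed here.

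Transcripts of cytosolic ribosomal proteins were lower by a modest amount across most members. Of 79 members 59 fell and 1 rose, with a median log2 fold change of −0.39 (−0.40 in batch 2, −0.37 in the untagged libraries). The list's adjusted p was 1.4e-08 at a preset correlation and 0.617 with an estimated correlation. Rpl13 fell from 2701 ± 188 to 1466 ± 232 FPKM (SD, n = 5; log2 −0.93 ± 0.10, adjusted p = 1.2e-05), Fau by 0.79 ± 0.09 and Rpl7a by 0.83 ± 0.10. In the untagged libraries alone no member was called, where the test on simulated data recovered 0% of 2-fold changes. Levels are relative to the total of each library, so a change in the RNA content of the embryos would not show. Ribosome biogenesis genes were mixed, with 9 of 29 rising and 6 falling. Utp15 and Wdr43 of the small-subunit processome rose by 1.26 ± 0.16 and 1.24 ± 0.18, and the nucleolin gene Ncl fell by 0.79 ± 0.13.

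Single chromatin regulators changed, while none of their 5 lists passed camera at a preset correlation (adjusted p from 0.45 to 0.97). By fry, which does not compare with other genes, histone acetylation (adjusted p = 0.00751) and DNA methylation (0.0437) moved on balance one way. The lists of H3K4, H3K9 and H3K27 methylation did not (fry adjusted p = 0.55, 0.261 and 0.915). Calls of single members are common here, since 49.4% of all tested genes were called. The 3 genes named per list are those with the smallest p, so they do not set these lists apart. For H3K4 methylation 4 of 12 rose and 3 fell: the demethylase gene Kdm5b rose by 1.07 ± 0.15, while Ash2l, a core subunit of the methyltransferase complexes, fell by 1.24 ± 0.14 and the demethylase gene Kdm1a by 1.03 ± 0.17. For H3K9 methylation 7 of 16 rose and 2 fell; the methyltransferase gene Ehmt1 rose by 1.10 ± 0.20, and the heterochromatin proteins Cbx1 and Cbx5 fell by 1.41 ± 0.17 and 1.04 ± 0.17. For H3K27 methylation and Polycomb 2 of 15 rose and 3 fell, with Pcgf6 rising by 0.66 ± 0.15, and Kdm6b and Jarid2 falling by 0.93 ± 0.20 and 0.59 ± 0.19. The call of Jarid2 was lost with limma rescaled to TPM (adjusted p = 0.0527) and with no trend (0.0547). For histone acetylation 3 of 19 rose and 6 fell. The acetyltransferase gene Hat1 fell by 1.03 ± 0.16 and the deacetylase genes Hdac3 and Hdac2 by 0.96 ± 0.16 and 0.53 ± 0.10. For DNA methylation 2 of 11 rose and 5 fell. The de novo methyltransferase gene Dnmt3b fell by 1.95 ± 0.31 and its relative Dnmt3a rose by 0.84 ± 0.15.

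Stress genes rose and fell side by side. In the integrated stress and unfolded protein response, 10 of 23 fell and 6 rose. Ddit4 rose from 4.74 ± 1.32 to 32.9 ± 4.82 FPKM (SD, n = 5; log2 2.79 ± 0.20, adjusted p = 1.1e-06) and the co-chaperone gene Dnajb9 rose by 2.24 ± 0.22, while the chaperone gene Hsp90b1 fell by 1.23 ± 0.13. Among immediate early and heat shock genes 5 of 12 rose and 1 fell, with Hspa1b rising by 3.09 ± 0.43, Myc by 1.72 ± 0.21 and Dnajb1 by 1.10 ± 0.17. Among interferon-stimulated and RNA-sensing genes 7 of 11 rose and 1 fell. Oasl2 rose by 1.47 ± 0.26, Irf9 by 1.39 ± 0.30 and Stat2 by 1.38 ± 0.26. Of 24 genes of p53 targets and apoptosis 21 were not called; Mcl1 and Aen rose by 1.04 ± 0.14 and 0.60 ± 0.18 (adjusted p of Aen 0.0873 with no batch term), and Bax fell by 0.77 ± 0.12. In cell cycle and DNA replication 11 of 33 fell and 2 rose. The ribonucleotide reductase genes Rrm1 and Rrm2 fell by 1.15 ± 0.19 and 0.90 ± 0.11, and the spindle checkpoint gene Mad2l1 rose by 0.71 ± 0.12.

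Imprinted genes moved both ways, with 5 of 14 rising and 6 falling. Usp29 rose by 2.51 ± 0.32, with 14.3% of its exon bases overlapping Zim3 on the opposite strand. Snrpn fell by 1.28 ± 0.14 and Snurf by 1.70 ± 0.25; Snurf lies fully within Snrpn exons, so its fall is not separate from that of Snrpn, while most exon bases of Snrpn lie outside Snurf. Among Y-linked and X-inactivation genes 3 of 5 fell. Xist, which silences the X chromosome, fell by 1.23 ± 0.21, and the Y-linked Eif2s3y by 1.20 ± 0.29, although none of its 5 Mettl3-ASO values lay below every control. Tsix, which overlaps Xist on the opposite strand, had −0.53 ± 0.21 (adjusted p = 0.0481; 0.0576 with the replicate block). Its adjusted p was 0.0588 to 0.125 when any library other than ASO-Control replicate 4 was left out, 0.432 in batch 2 and 0.0739 to 0.101 with limma.

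Markers of other cell types were few. Of 19 cumulus and granulosa genes 1 was tested, Nr5a2, which embryos also express and which rose by 1.10 ± 0.19. Of 15 sperm and testis genes 1 was tested, Odf2, with −0.36 ± 0.17 (adjusted p = 0.0948; 0.0367 with the replicate block, 0.0458 without ASO-Control replicate 4, 0.0317 under quantile scaling and 0.0401 with library weights). Of 13 blood and immune genes 4 were tested and 2 fell: Cd74 by 0.87 ± 0.21 and Cd68 by 0.99 ± 0.31, neither of which was called in batch 2 alone (adjusted p = 0.0929 and 0.111). The adjusted p of Cd68 was 0.0589 without ASO-Control replicate 1 and 0.053 without ASO-Control replicate 4. Hba-a2 had counts in ASO-Control replicate 5 (66) and in Mettl3-ASO replicates 1, 2 and 3 (83, 91 and 74), and none in the other libraries. Its log2 fold change was 2.08 ± 1.70 (adjusted p = 0.33), with 0.33 in batch 2 (adjusted p = 0.897), fitted values of 9.53 in the untagged libraries (adjusted p = 0.0182) and 8.82 without ASO-Control replicate 5 (adjusted p = 0.0127), and its adjusted p was 0.00256 with no filter. The values of 9.53 and 8.82 are set against controls with no counts and depend on the prior count. At a floor of 3 counts over the group Hba-a2 was 60.8-fold and 71.2-fold higher there, which covers counting error only. Of the 50-base windows of Hba-a2, 89.3% occur in other genes. Its counts of 0 may thus reflect how reads were shared out, and neither fold is a firm lower bound. The most abundant marker, Hba-a1, had 44.8 ± 13.5 FPKM in ASO-Control and 39.5 ± 15.2 in Mettl3-ASO (SD, n = 5; adjusted p = 0.631).

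Of the 120 named genes 115 were called. In 99 of these all 5 Mettl3-ASO libraries lay beyond all 5 controls. Chance separates 0.794% of genes not chosen by their values in this way, but most of the named genes were chosen by a small p or a large change, so their count only describes them. In batch 2 alone 112 of the 120 were called, and in the untagged libraries alone 48. Reads of genes that overlap on opposite strands cannot be told apart unless strand was used, which holds for 30.5% of the exon bases of Mrps18b, 18.7% of Igf2bp3, 17.6% of Cbll1 and 13.9% of Mrpl47. Windows of 50 bases that occur in other genes made up 77.9% of Gm5662, 62.3% of Hspa1b, 38.4% of Atp5g2, 37.9% of Rpl7a, 31.4% of Tcstv3 and 26.0% of Eno1, so that their values are uncertain.

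Tested as lists against all other genes at a preset correlation, 5 of 31 lists passed. They were the two-cell-stage genes (up) and the cytosolic ribosomal proteins, trophectoderm, TCA cycle and glycolysis (down). The other 26 had adjusted p from 0.0747 to 0.97. With no filter 10 lists passed, adding complexes I and V, mitochondrial ribosomal proteins, compaction and cell cycle, and compaction passed in the untagged libraries (0.0279). With an estimated correlation no list passed, the lowest adjusted p being 0.181, and 1 had an unadjusted p under 0.05. Of 100 splits of the 10 libraries into groups of 5, the real one included, 49 gave 5 or more such lists. fry found 21 lists moving on balance one way and 30 with members changed in either direction. Counts of called members adjusted over the list alone differed in 5 lists: 14 TCA genes fell, 5 readers and erasers fell, 1 primitive endoderm gene fell, 60 ribosomal protein genes fell, and 1 Y-linked or X-inactivation gene rose beside the 3 that fell. Median, mean and test differed in sign for 5 tested lists: the methyltransferase complex (median 0.47, mean −0.74), antioxidants, H3K4 methylation, H3K27 methylation and imprinted genes (median −0.38, mean 0.27).

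**Figure D3:**
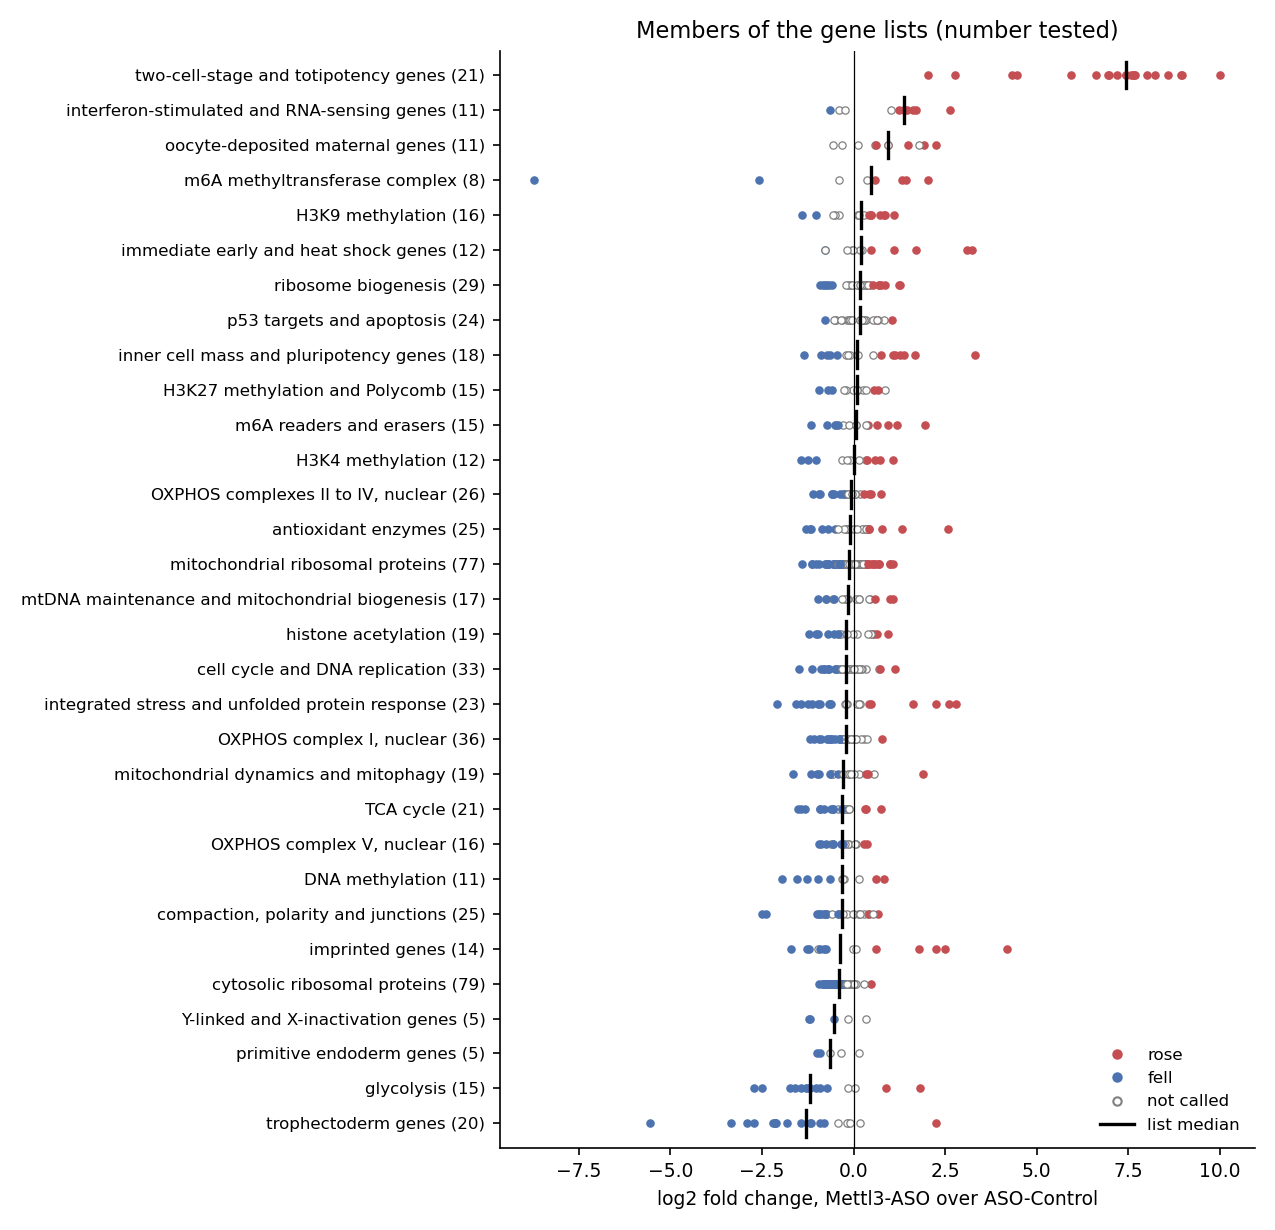
Log2 fold changes (horizontal) of the tested members of 31 gene lists, one line per list with its number of members; filled points were called, red for a rise and blue for a fall, and open points were not. Black bars are list medians, from −1.31 for trophectoderm genes to 7.43 for two-cell-stage genes.

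The response was compared between batches, which share no library. Fold changes of the 9522 genes correlated at Pearson's r = 0.887 and Spearman's rho = 0.876 across genes. All 596 genes called in the untagged libraries had the same sign in batch 2, and 579 were called in both. Over 60 relabellings of groups within batches, the correlation of log count differences, 0.894 for the real labels, was not reached by any other and was at most 0.712. For no gene did edgeR find the response to differ between batches, with 159 at an unadjusted p under 0.05 (0 and 243 with the replicate block). On simulated counts this test recovered 4.48% of 2-fold and 36.4% of 4-fold differences, so its result does not show equal responses. With limma on log2(FPKM + 1) the count was 0 (170 unadjusted). DESeq2 gave 1, Crip1 (172 unadjusted), named after its values were seen. Without Mettl3-ASO replicate 2 edgeR called 2 genes, Gm5424 and Lrp2, and without Mettl3-ASO replicate 4 it called 1, Zscan4c.

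**Figure D4:**
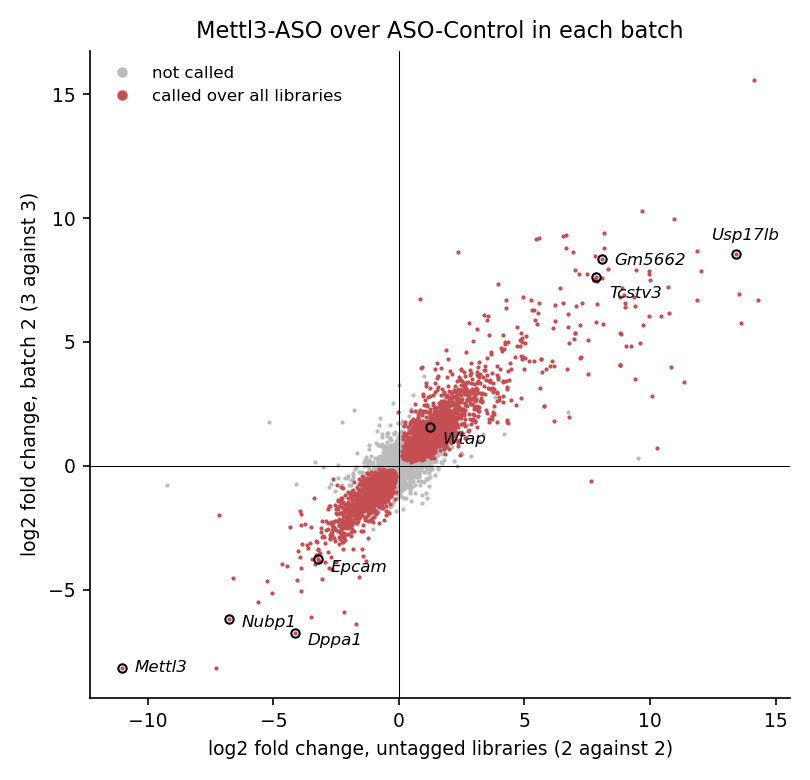
Log2 fold change of Mettl3-ASO over ASO-Control in the 4 untagged libraries (horizontal) and the 6 libraries of batch 2 (vertical) for the 9522 tested genes, with genes called over all libraries in red. The values correlate at r = 0.887, and Mettl3 lies at the lower left at fitted values of −11.02 and −8.17, of which the first is set against no counts and depends on the prior count.

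More genes were detected in Mettl3-ASO libraries. Genes at an FPKM of at least 1 numbered 9525 ± 408 against 8979 ± 427 in ASO-Control (SD, n = 5; exact permutation p = 0.0167, the smallest possible). The mean difference within batches was 546 genes, with 9272 against 8681 in batch 2 and 9904 against 9426 in the untagged libraries. Paired by replicate number, the exact permutation p was 0.0625, the smallest that 5 pairs allow.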

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

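The test of isoform-weighted length was added after the data were seen; the rule for values far from their group was set in the plan. Over the named genes, the total count and the number of detected genes, 24 of 244 groups of 5 values (9.84%) held a library whose gap to the nearest other value exceeded 0.71 of the group's range. Chance gives about 1 in 20 groups. Mettl3-ASO replicate 1 was that library in 14 cases, where it was the highest of its group. In FPKM it held Dppa1 at 6.4 (others 0.24 to 0.41), Epcam at 79.22 (15.53 to 21.56), Serpinb9b at 22.99 (6.18 to 10.44), Igf2bp3 at 7.19 (2.48 to 3.64) and Chchd3 at 38.52 (9.76 to 17.62). It held Aldoa at 266.5 (103.88 to 138.92), Slc2a3 at 20.34 (6.29 to 9.68), Sod2 at 77.07 (39.37 to 49.67), Kdm6b at 3.37 (1.2 to 1.66) and Cldn6 at 23.65 (2.8 to 6.97). It also held Lamb1 at 12.38 (1.86 to 4.71), Sparc at 5.12 (0.73 to 1.37), Cldn7 at 227.91 (90.14 to 121.2) and Rpl7a at 885.27 (586.1 to 661.53).

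In the other libraries of Mettl3-ASO, Ythdf2 was highest in replicate 2 at 102.39 FPKM (others 77.99 to 82.07) and Ddit4 was lowest in replicate 3 at 24.67 (33.7 to 37.33). In ASO-Control, Rpl7a reached 1365.46 in replicate 1 (1081.49 to 1141.67) and Mcl1 49.98 in replicate 1 (26.63 to 32.54). Cbx5 reached 15.96 in replicate 2 (10.27 to 11.91), Zp3 2.81 in replicate 2 (1.12 to 1.34), Nubp1 61.37 in replicate 3 (52.27 to 54.04) and Mad2l1 175.65 in replicate 4 (146.7 to 154.57). Usp17lb at 0.74 and Hba-a2 at 6.12 had values above 0 only in replicate 5 among the controls.

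The length of each gene averaged over its transcripts, weighted by their estimated abundance, is a deposited measure that the edgeR test of counts does not use. FPKM values, and so the filter and the limma alternatives, depend on it. It differed between groups in 221 of 2532 genes tested with limma, 61 longer and 160 shorter in Mettl3-ASO, with 597 at an unadjusted p under 0.05. The median absolute log2 difference of the 221 was 0.0293. Among genes chosen after their values were seen, Wtap was shorter, at 2493 ± 99.8 bases in ASO-Control and 2099 ± 13.9 in Mettl3-ASO (SD, n = 5; adjusted p = 0.00259), and Tor1aip2 was longer, at 2676 ± 7.55 and 3412 ± 228 (SD, n = 5; adjusted p = 0.00199). The count was 96 with the replicate block, 69 in batch 2 and 4 in the untagged libraries. It was 140, 134, 129, 137 and 125 without ASO-Control replicates 1 to 5 in turn. Of 100 splits of the libraries 1, the real one, gave as many genes, and the highest other gave 25. Over all splits this excludes chance for the count only if the libraries are not paired. Of the 10 splits that part all pairs the highest other gave 3, and 10 are too few for a share under 0.05.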

How the results depend on the processing

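Robust edgeR, scaling without the 50 highest genes and the two-cell list, and leaving out libraries for within-batch counts and for the correlation between batches, and the replicate block for that correlation and the interaction were chosen after the data were seen. The count of 4704 called genes was 596 in the untagged libraries alone, 3052 with an exact Wilcoxon test and 2106 with a 2-fold threshold added. The untagged setting uses fewer libraries and the last a stricter call. The Wilcoxon test also drops the batch term, which alone gave 3949; in simulated data with few changed genes it recovered 0% of changes. It was 3281 to 5864 under the remaining settings, which include limma, DESeq2 (4952) and each library left out (4194 to 4800). With the replicate number as a block it was 5246, of which 4667 were among the 4704. No gene called in both changed direction in any setting. The median of all genes moved by at most 0.0541 between scalings, but scaling itself largely sets this median. A shift common to all genes would not show. The level of Mettl3 kept its direction and call in each setting that tested it; a mean FPKM of at least 5 removes it.

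The untagged count of 596 was 300 with limma, 371 at a mean FPKM of at least 5 and 1572 with DESeq2. It was 2606 with the replicate block, which leaves little to estimate spread from. Without 1 library it was 94 to 2652 (94 without ASO-Control replicate 2, 245 without ASO-Control replicate 1, 1063 without Mettl3-ASO replicate 2, 2652 without Mettl3-ASO replicate 1); the group that loses a library then holds 1, which is assumed to vary like the other group, and the cause was not tested. The batch 2 count was 2711 to 3412 without 1 library. Genes whose response differed between batches numbered 0 in edgeR, also with the replicate block, and limma, 1 in DESeq2, and 0 to 2 without 1 library, of which 2 without Mettl3-ASO replicate 2 and 1 without Mettl3-ASO replicate 4; the cause was not tested. The correlation between batches was 0.921 at a mean FPKM of at least 5, 0.874 with the replicate block and 0.788 to 0.888 without 1 library. The difference of 546 detected genes had an exact permutation p of 0.0625 with the replicate block, where 5 pairs allow no smaller one. Of the lists, 10 were called with no filter, 0 with an estimated correlation and 21 by fry, which tests something else; the other settings gave 4 to 7.

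In the untagged libraries 68 named genes lost their call and 1, Hba-a2, gained one. With the exact Wilcoxon test 13 lost it: 1110037F02Rik, Igf2bp3, Tefm, Aldoa, Kdm6b, Jarid2, Dppa3, Lamc1, Lamb1, Cldn7, Aen, Eif2s3y and Tsix. In each other setting at most 5 did. Member counts of 3 or fewer moved by over 1.5 times, or from 0, when a library was left out. Primitive endoderm genes that fell went from 2 to 1 without each ASO-Control replicate but 2 and without Mettl3-ASO replicates 3, 4 and 5. Glycolysis genes that rose went from 2 to 1 without each library but ASO-Control replicate 4. Complex V genes that rose went from 2 to 1 without ASO-Control replicates 2, 3 and 5 and Mettl3-ASO replicates 3, 4 and 5. Complex I genes that rose went from 1 to 2 without ASO-Control replicates 1 and 4 and Mettl3-ASO replicates 1 and 2. Mitochondrial dynamics genes that rose went from 3 to 1 without ASO-Control replicates 1, 3 and 5 and Mettl3-ASO replicates 3 and 4, and TCA genes that rose from 3 to 1 without ASO-Control replicates 1, 2 and 3 and Mettl3-ASO replicate 3. H3K27 genes that rose went from 2 to 1 without ASO-Control replicates 1 and 2 and Mettl3-ASO replicate 5. Without Mettl3-ASO replicate 1, genes that rose went from 2 to 5 for the cell cycle, from 3 to 5 for histone acetylation and from 2 to 4 for p53 targets (4 also without ASO-Control replicate 5), and genes that fell from 3 to 5 for mtDNA maintenance, from 1 to 3 for immediate early genes and from 0 to 2 for oocyte-deposited genes. p53 targets that fell went from 1 to 2 without ASO-Control replicate 4 or Mettl3-ASO replicate 2 and to 3 without Mettl3-ASO replicate 5, and immediate early genes that fell to 2 without ASO-Control replicate 4 or Mettl3-ASO replicate 5. Blood genes that fell went from 2 to 1 without ASO-Control replicate 1 or 4 and those that rose from 0 to 1 without ASO-Control replicate 5. A Y-linked or X-inactivation gene rose without ASO-Control replicate 4 or Mettl3-ASO replicate 1, and 1 sperm gene fell without ASO-Control replicate 4. At the depth and number of the untagged libraries, simulated 2-fold changes were recovered in 0% and 4-fold changes in 51.5% of cases; depth was not varied alone.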

Other observations

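Beyond the lists fixed in the plan, genes were grouped by the stem of their symbol into 131 families of at least 8 tested members. The families, the choice of copy groups with a tested member, the test of copy groups that rose under 2-fold, the share of the highest genes, the test of a common admixture, and the tests of splits for single lists were chosen after the result was seen. Kelch-like genes, many of which encode adaptors of Cul3 ubiquitin ligases, rose in 11 of 14 cases with none falling (median 0.99, adjusted p = 0.0192 at a preset correlation, 0.907 with an estimated correlation). Klhl11 rose by 1.98 ± 0.32, Klhl21 by 1.54 ± 0.19 and Klhl10 by 1.38 ± 0.21. The Rpl and Rps families were called as well (adjusted p = 0.00684 each, 0.907 with an estimated correlation). Of 8 subunit genes of the chaperonin Cct 6 fell and none rose (adjusted p = 0.0823); Cct6a fell by 0.82 ± 0.11 and Cct4 fell by 0.81 ± 0.10. Of 8 annexin genes 6 fell and none rose (adjusted p = 0.12); Anxa2 fell by 2.57 ± 0.24. Of 222 Zfp genes 76 rose and 19 fell (adjusted p = 0.0915). Of 100 splits, 34 gave 3 or more families (real 3, highest other 8), so chance is not excluded for these calls.

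Other strong falls, chosen after their values were seen, were in Tbl1xr1, a subunit of nuclear corepressor complexes, which fell by 7.76 ± 0.43, and in Nr6a1, an orphan nuclear receptor, which fell by 4.88 ± 0.52. Por, which passes electrons to cytochrome P450 enzymes, fell by 4.26 ± 0.31. Among ribosomal protein genes Rpl41 rose by 0.47 ± 0.11.

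The number of called genes, 4704, was reached in 1 of 100 splits of the libraries into groups of 5, the real one. The highest other gave 1. Over all splits this excludes chance only if the libraries are not paired. Of the 10 that part all pairs 1 was as large and the highest other gave 0, but 10 are too few for a share under 0.05; the other 90 keep 1 or more pairs in one group. Within batch 2 the real split gave 3718 and the highest other 0, but 10 splits, of which 1 was as large, are too few for a share under 0.05. For the count of 5 gene lists chance is not excluded: 49 of 100 splits gave as many, with a highest other of 9, and 4 of the 10 splits that part all pairs gave as many, with a highest other of 7. For single lists, camera gave a p as small in 23 of 100 splits for glycolysis, 16 for trophectoderm and 5 for the TCA cycle. Chance is thus not excluded for these calls. It also gave a p as small in 5 splits for the two-cell list (−log10 p 15.3, highest other 19.3). For the ribosomal protein list it did so in 18 (9.04, highest other 16.3), so chance is not excluded for either list call. Counts of called members were reached by 1 split, the real one, in both the two-cell and the ribosomal protein list. They were 21 two-cell genes (highest other 0) and 60 ribosomal protein genes in either direction (highest other 0). No other split called more than 1 gene of all tested genes, so none could reach these counts, which thus decide nothing for the lists. The absolute list median was as large in 2 of 100 splits for each list, the real one included. It was 7.43 for two-cell genes (highest other 7.44) and 0.388 for ribosomal proteins (highest other 0.393).

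The rise of two-cell-stage genes in Mettl3-ASO was weighed against several technical explanations. Reads moved between gene copies would leave summed copies level, but sums over 10 groups of genes that share sequence with the 21 tested members had a median log2 ratio of 2.75 and were higher in 10 of 10, in 7 of them above all controls in each Mettl3-ASO library (in 3 of 5 libraries for the Zscan4 group). For 2 groups, with Sp110 and Zfp352 at 0.68 and 0.84, sharing of reads stays open. Counts of other genes enter these sums (the Sp110 group pools 52 genes), so a low ratio does not speak for sharing. The Zfp352 sum lay above all controls in 5 Mettl3-ASO libraries and the Sp110 sum in 4. A few genes taking most of the counts is argued against by the share of the 10 highest genes, at most 10.8% of the counts of any library. One common admixture of arrested two-cell embryos would keep its genes in one ratio, but Zscan4 to Tcstv3 plus Zfp352 differed 2130-fold between Mettl3-ASO libraries; embryos arrested at different times stay open. An effect of lower Mettl3, which the design names, may account for the rise but was not tested apart from injection of this oligonucleotide.

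The lower level of ribosomal protein transcripts was weighed against gene properties and scaling. Of 10000 lists matched on length, GC and mean count, 0% had a median as low as −0.39, and the lowest had −0.31. The matched lists fell as well, with a median of −0.11, and their genes lay at a mean distance of 0.683 SD from the members. Matched genes were drawn singly, while the list's estimated correlation was 0.402. The spread of matched lists may thus be too narrow, and the share of 0% is not a p-value. Minus the median of all genes, the list median was −0.40 to −0.21 over 7 scalings, but one factor per library moves the list and all genes alike, so this difference was largely fixed and library scaling stays open. A share of embryos at another stage and an effect of lower Mettl3 may each account for it and stay open, since developmental stage was not measured apart from these libraries.

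Strong falls besides Mettl3 could come from the oligonucleotide pairing with other transcripts. The most shared 12-base window of the Mettl3 transcript occurred in 5 of 24 strongly fallen genes, and in matched gene sets the median was 5 and the 95th percentile 7. That window is a run of T ending in A, which says little of an oligonucleotide site. Among windows found in under 1% of the matched genes, the most shared occurred in 2 fallen genes (median 2 and 95th percentile 2 in matched sets). Neither count is an excess. Introns and imperfect pairing were not searched, and the sequence of the oligonucleotide is not given in the sources used here. Pairing with other transcripts and an effect of lower Mettl3 thus cannot be told apart.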
